A study of Rattus norvegicus with 23 samples.

How the data were processed

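Small RNA from female Sprague-Dawley rats was measured on 23 Agilent miRNA arrays of 1 colour (Cy3): 8 spontaneous mammary carcinomas, 8 radiation-induced mammary carcinomas and 7 normal mammary tissues. Per the labels' protocols, total RNA was extracted with a column kit, dephosphorylated and labelled at its 3' end with pCp-Cy3 by RNA ligase. The deposited scanner files hold spot intensities on a linear scale made with Agilent Feature Extraction 9.5.1.1, per the file headers. The processed signal in them is background-subtracted within each array and not normalized between arrays. The authors' deposited value table holds the total gene signal of the same arrays as intensity on a linear scale: 100% of its values above its lowest value of 5 equalled the scanner files' total gene signal within 1%, for all 350 miRNAs. It has no centring and no normalization between arrays, and the origin of its lowest value is not given in the sources used here. Its medians per array ran from 5 to 18.9.

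Each array holds 7000 miRNA spots and 953 control spots, and the control spots were left out. The processed signal was averaged over the spots of each of 938 probes that had no outlier mark. Saturated spots were kept. A probe was taken as detected on an array where most of its spots were well above background. As 35.7% of probe values were detected, each array was scaled by its 75th percentile over the 199 probes detected on all 23 arrays. Scaled signals were floored at 9.81 (log2 3.29), the median over arrays of the lowest signal well above background, and then log2-transformed. The floor can understate a difference from a group near it. On all 8 spontaneous arrays the lowest signal well above background lay above the floor (12.0 to 29.7). Signals between the 2 levels are not well above background, so differences that rest on them may also be overstated. Of the tested miRNAs, 196 had several probes, and each was represented by the probe with the highest mean over all arrays. The 199 miRNAs with a probe detected on at least 7 arrays were tested. Names are those of the array design, and 195 of the 199 matched a gene of the RefSeq table of assembly GRCr8. The array headers name build rn4, so that table was used only for neighbouring genes and no coordinates are given.

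Groups were compared with limma 3.58.1 in R 4.3.3, with files read by the package data.table (version 1.17.8), with 1 mean per group over all 23 arrays, which share 1 estimate of the spread (total degrees of freedom 22.5). P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and errors of differences are standard errors (SE) of this model. A miRNA was counted as radiation-specific where it passed in the same direction against both other groups. Where no array of a group had a miRNA well above background, the fold is a lower bound. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the miRNA's own signal. Arrays of the brighter group without the miRNA well above background kept their floored signal. Where there were such arrays the bound is approximate. The text names the 12 miRNAs with the largest rise and the 12 with the largest fall that passed in each comparison, the radiation-specific ones, up to 4 members with the smallest p of a list discussed, and miR-192 and miR-194 (miR-215, of the same family, was not among those tested). Lists discussed with examples are those that passed with a preset correlation. The 27 lists of families, clusters and cell type markers were tested with limma's camera with an estimated correlation, adjusted over 75 tests. Where a camera p stands before one with an estimated correlation, it used the alternative preset correlation of 0.01. For the lists discussed with examples the estimated correlation ran from 0.17 (p53-responsive) to 0.88 (X-linked cluster). The p-values with the preset correlation can therefore be too small. Exact two-sided permutation tests were used for miR-194, miR-192 and 3 measures of the arrays. These choices were made before the data were examined, except which lists are discussed with examples, which was set after their tests had been seen.

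Array precision rests on the number of arrays, and no counts underlie the values. The carcinoma codes name 16 different animals. The labels do not say whether the normal tissues came from separate animals, so p-values against them may partly measure technical spread. The arrays lie on 4 slides, each scanned once on 1 day, so scan and slide are the same batch. Slide 4 holds all 3 groups, slides 1 and 2 hold spontaneous carcinomas and normal tissues, and slide 3 holds radiation-induced carcinomas and normal tissues. Correlations between arrays ran from 0.607 to 0.993, so no pair of arrays held the same values.

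Alternatives covered the scaling (percentile over all probes, quantile, none), the background (normexp with offset 50, on the median signal because the files have no mean signal), the total gene signal, the deposited table, the mean of all probes, the filter, a floor 4 times lower, trend and robust options, array weights, slide as a fixed block, only the arrays of the compared groups, only the spontaneous carcinomas whose code starts with M (as all radiation-induced ones do) and leaving out each array. After the data were seen, 4 more were added: leaving out 2 carcinomas without the miR-200 family, the same with slide as a block, a raised floor, and array brightness as a covariate. The procedure was tested on simulated data with 40 of 199 miRNAs changed between radiation-induced and spontaneous carcinomas: 10 of 20 changed by log2 1 and 19 of 20 changed by log2 2 were called, with 1 call among 159 unchanged. The simulated noise was independent, with 1 spread per miRNA for all groups. It held no slide differences, dimmer arrays or outlying arrays, so the test does not cover these. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3).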

Results

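MicroRNA levels were measured in rat mammary carcinomas that arose spontaneously (n = 8) or after radiation (n = 8) and in normal mammary tissue (n = 7), to find miRNAs specific to the radiation-induced carcinomas. Spontaneous carcinoma arrays were dimmer and detected fewer miRNAs than the others. They detected 164 ± 7.27 miRNAs (SD, n = 8, from 154 to 174), against 188 ± 10.6 (SD, n = 8, from 169 to 206) on radiation-induced and 195 ± 13.9 (SD, n = 7, from 180 to 212) on normal tissue arrays. The 75th percentile before scaling was 604 ± 175 in spontaneous, 1161 ± 393 in radiation-induced and 1562 ± 560 in normal samples (SD). In exact permutation tests the spontaneous arrays lay below the radiation-induced ones (p = 0.000466, adjusted p = 0.00105, 8 of 8 radiation-induced arrays above the spontaneous mean) and below normal tissue (p = 0.000155, adjusted p = 0.000698, 0 of 8 spontaneous arrays above the normal mean) in both measures. The difference between radiation-induced and normal arrays did not pass these tests (exact p = 0.309 for detection and 0.131 for brightness). The 10 brightest miRNAs took 49.8% ± 3.67, 52.3% ± 3.83 and 50.1% ± 2.25 of the signal (SD), with exact p of 0.21, 0.207 and 0.868 for the 3 pairs of groups. Only 3 spontaneous carcinomas share the M codes of all radiation-induced ones, and they lie on slide 4 while the 5 others lie on slides 1 and 2. With these 3 alone, exact permutation tests called 0 of these differences instead of 4 (3 at an unadjusted p under 0.05). Their mean number detected was 164 and their mean 75th percentile 678.

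The miR-200 family, which marks epithelial cells, was detected in 7 of 8 spontaneous and 7 of 8 radiation-induced carcinomas and at the floor in the remaining 1 of each kind. In spontaneous carcinoma 1 and radiation-induced carcinoma 3, miR-141, miR-200a, miR-200b, miR-200c and miR-429 all lay at log2 3.29. The lowest other spontaneous carcinoma had miR-200c at 12.20 and the lowest other radiation-induced one at 11.83. Both samples stayed in all comparisons, and the number of calls in each comparison, of radiation-specific miRNAs and of shared miRNAs is also given without them.

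**Figure D1:**
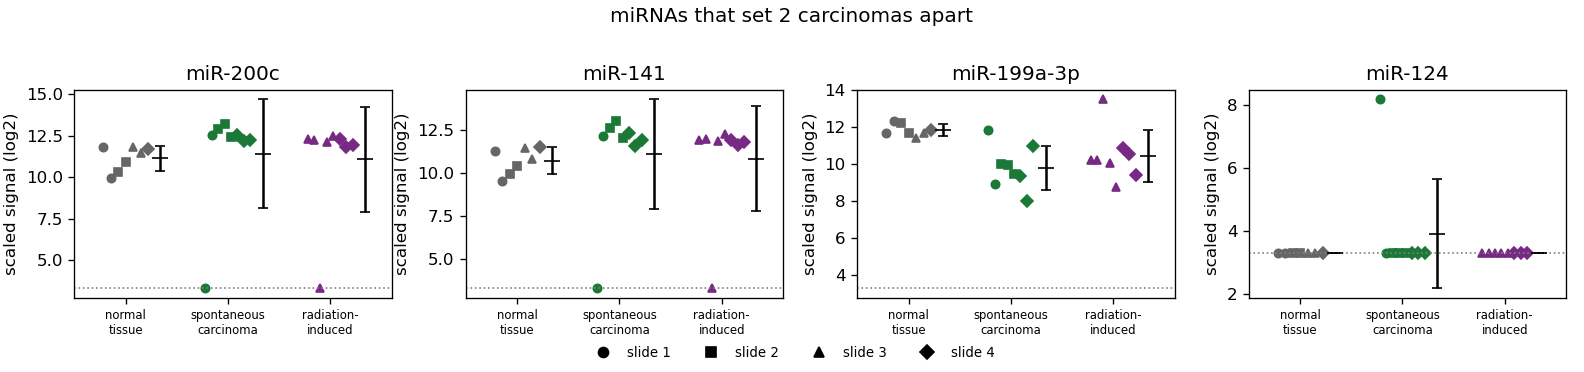
Scaled log2 signal of 4 miRNAs on each array by group, with the marker shape giving the slide, the bar giving mean ± SD and the dotted line the floor. miR-200c and miR-141 lay at the floor (3.29) in 1 spontaneous and 1 radiation-induced carcinoma, the latter had the highest miR-199a-3p (13.51), and the former alone had miR-124 above the floor (8.21).

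Radiation-induced carcinomas had more of the p53-regulated miR-34b and miR-34c than spontaneous ones, by 2.85-fold and 2.66-fold (log2 1.51 ± 0.43 and 1.41 ± 0.39, SE, n = 8 and 8). The largest rise was in miR-135b, 3.85-fold (log2 1.95 ± 0.49), detected in 7 of 8 radiation-induced and 1 of 8 spontaneous carcinomas. miR-221 and miR-222, neighbours in the genome that target the cell cycle inhibitor p27, rose 2.16-fold and 2.47-fold, with miR-222 detected in 1 of 8 spontaneous carcinomas and lower with normexp (log2 -0.28). The neighbouring miR-195 and miR-497 rose 2.81-fold and 2.94-fold, and the neighbouring miR-143 and miR-145, abundant in smooth muscle and fibroblasts, 2.46-fold and 2.57-fold, though miR-145 was lower with normexp (log2 -0.10). The largest fall was in miR-483, which lies in an intron of Igf2, by 6.29-fold (log2 -2.65 ± 0.80).

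Of 199 miRNAs, 16 were higher and 20 lower in radiation-induced carcinomas (11 and 12 by at least 1 on the log2 scale, 70 at an unadjusted p under 0.05). The other leading rises were miR-125b-5p (log2 1.32 ± 0.28), miR-29a (1.04 ± 0.29) and miR-100 (0.93 ± 0.24). All leading rises had adjusted p from 0.0121 to 0.0367 and lay above the spontaneous mean in 8 of 8 carcinomas, except miR-135b in 6 of 8. The leading falls after miR-483 were miR-466b (log2 -1.60 ± 0.52), miR-503, miR-672, miR-18a, miR-542-3p, miR-450a, miR-539, miR-333, miR-340-3p, miR-340-5p and miR-99b* (-1.01 ± 0.26). Their adjusted p ran from 0.0121 to 0.0457, and each was below the spontaneous mean in at least 7 of 8 carcinomas. Among 8 tested members of the p53-responsive list, 5 rose and 1 (miR-107, log2 -0.56 ± 0.16, but 0.38 unscaled and 0.37 in the deposited table) fell, or 7 and 1 adjusted over the list alone. The 5 were miR-34b, miR-34c, miR-194, miR-143 and miR-145. Of these, miR-143 and miR-145 are also the 2 of 6 that rose in the smooth muscle and fibroblast list. The list's median of 1.11 was -1.87e-05 with normexp. Its camera test gave adjusted p = 0.00803 with the preset correlation and adjusted p = 0.513 with an estimated correlation. Of 7 members of the X-linked miR-322 to miR-450a cluster, 3 fell (miR-503, log2 -1.54 ± 0.49, miR-542-3p and miR-450a) and miR-351 (log2 -0.79 ± 0.30, adjusted p = 0.0732, lower in 7 of 8) did not pass. Adjusted over the list alone, 6 fell (camera adjusted p = 0.016, and adjusted p = 0.586 with an estimated correlation).

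Of the miR-17 to miR-92 cluster and its paralogues, which promote proliferation, miR-18a (log2 -1.39 ± 0.43) and miR-93 (-0.79 ± 0.24) fell among 11 tested members, and 3 fell adjusted over the list alone. Unscaled and in the deposited table miR-93 was at 0.15 and 0.13 and the list's median went from -0.56 to 0.30 and 0.27. miR-17-5p (log2 -0.97 ± 0.35) and miR-20a (-0.84 ± 0.34, but 0.097 unscaled and 0.080 in the deposited table) did not pass (camera adjusted p = 0.0166, and adjusted p = 0.704 with an estimated correlation). In the miR-34 family, 2 of 3 members rose, and 3 adjusted over the list alone, with miR-34a at log2 0.92 ± 0.35, or 0.54 without spontaneous carcinoma 1 (camera adjusted p = 0.0216, and adjusted p = 0.513 with an estimated correlation). Both members of the miR-221 and miR-222 list rose, also adjusted over the list alone (camera adjusted p = 0.0347, and adjusted p = 0.513 with an estimated correlation). Of the miR-99a, miR-100 and miR-125b list, 2 of 4 rose, as adjusted over the list alone, and miR-99a (log2 0.80 ± 0.37, or 0.51 without spontaneous carcinoma 1) and miR-99a* (0.48 ± 0.32, -0.47 with normexp and -0.091 with the raised floor) did not pass (camera adjusted p = 0.0166, and adjusted p = 0.513 with an estimated correlation). In the miR-29 family 1 of 5 rose, and 4 adjusted over the list alone, with miR-29b at log2 0.72 ± 0.31 and miR-29c, which is also the list's median, at 0.68 ± 0.31, or 0.42 without spontaneous carcinoma 1 (camera adjusted p = 0.0453, and adjusted p = 0.528 with an estimated correlation). Its other leading member, miR-29a*, was not well above background in any spontaneous carcinoma (log2 0.32 ± 0.13, -0.52 with normexp). Without both carcinomas lacking miR-200 the differences were -0.84 for miR-18a (adjusted p = 0.0547), -0.48 for miR-17-5p, -0.38 for miR-20a, 0.47 for miR-34a, 0.38 for miR-99a and 0.27 for miR-99a*. The miR-17 to miR-92 list then went from -0.56 to -0.20 and the miR-99a list from 0.86 to 0.53. With slide as a block the medians of these lists were 0.96 for the p53-responsive, -1.56 for the X-linked, -0.44 for the miR-17 to miR-92, 1.19 for the miR-34, 1.29 for the miR-221, 1.15 for the miR-99a and 0.61 for the miR-29 list. On slide 4, whose arrays are among those the lists were picked on, they were 0.77, -1.32, 0.030, 1.26, 1.75, 1.11 and 0.27.

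With slide as a block limma called 7 miRNAs, 4 higher (miR-135b, miR-125b-5p, miR-100 and miR-222) and 3 lower (miR-340-3p, miR-340-5p and miR-483), all 7 among the 36. On slide 4, the only slide with both kinds of carcinoma (3 and 3), limma called 2 higher and 1 lower, and all 36 differences had the same direction, though these arrays were among those that gave the 36 calls. The 36 miRNAs with the smallest p on slides 1 to 3 alone had the same direction on slide 4 in 31 of 36. Their median was 0.53 there against 1.21 on slides 1 to 3, which is raised because they were picked on those arrays. Fitted on the 16 carcinomas alone limma called 0 (58 at an unadjusted p under 0.05). The 36 calls thus depend on a spread estimated with the normal tissues included. Each normal tissue had a higher mean correlation with its own group than any carcinoma had with its own. The SE of differences between carcinomas may therefore be too small. With array brightness as a covariate limma called 0 (16 at an unadjusted p under 0.05). Against only the 3 M-coded spontaneous carcinomas, all on slide 4, it called 10. The balance of higher to lower calls moved with the scaling, and with the signal and background correction used, from 16 and 20 to 29 and 5 with the percentile over all probes, 15 and 5 with quantile normalization, 23 and 8 with the total gene signal, 99 higher and 0 lower unscaled or in the deposited table, and 11 and 97 with normexp. Without the 2 carcinomas lacking miR-200, 48 were called, 30 of them among the 36, and without radiation-induced carcinoma 7 or 1 the count was 20 or 23.

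Against both other groups, 6 miRNAs were specific to radiation-induced carcinomas: miR-135b, miR-34b, miR-34c, miR-221 and miR-194 were higher and miR-333 was lower. Both comparisons share the radiation-induced arrays, which favours overlap by chance. Another grouping of the carcinomas gave 8 such miRNAs, so the count of 6 alone does not show a radiation-specific pattern. miR-194, which the title of the study names, had a level of 4.37 ± 0.46 (SD, n = 8) in radiation-induced carcinomas. It was 3.71 ± 0.55 (SD, n = 8) in spontaneous ones and 3.35 ± 0.11 (SD, n = 7) in normal tissue. It was well above background in 7 of 8, 3 of 8 and 4 of 7 samples, and these levels lie close to the floor of 3.29. It was 1.57-fold higher than in spontaneous carcinomas (log2 0.65 ± 0.22, adjusted p = 0.0422, above the spontaneous mean in 7 of 8, exact permutation p = 0.0264). Against normal tissue it was 2.02-fold higher (log2 1.02 ± 0.23, adjusted p = 0.00285, 8 of 8, exact permutation p = 0.000311). Spontaneous carcinomas did not pass against normal tissue (log2 0.37 ± 0.23, exact permutation p = 0.114). That difference was -0.40 unscaled, -0.60 in the deposited table, -0.0021 with quantile normalization and 0.22 without spontaneous carcinoma 4. Its neighbour miR-192 was at log2 0.44 ± 0.17 against spontaneous carcinomas (adjusted p = 0.0791, 8 of 8, -0.47 with normexp and -0.015 with the raised floor), so 1 of 2 in that list rose, or 2 adjusted over the list alone (median 0.55, camera adjusted p = 0.528 with an estimated correlation). It rose against normal tissue by 2.05-fold (adjusted p = 0.000282, 8 of 8).

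Only miR-135b stayed specific with slide as a block (log2 2.71 against spontaneous carcinomas), and miR-194 then had adjusted p = 0.101 at log2 0.78 ± 0.28 (0.91 within slide 4). Over 18 alternatives, whichever the direction, its adjusted p ran from 0.00168 to 1. Fitted with limma on the compared groups alone or with the brightness covariate, 0 were specific because 0 were called between the carcinomas, and without the 2 carcinomas lacking miR-200 the count was 15. Without radiation-induced carcinoma 3 it was 11. Of the 6, 4 remained with the percentile over all probes and with quantile normalization, 3 with the total gene signal, 2 with normexp, and 1, miR-135b, unscaled or in the deposited table. However, miR-135b was not specific with normexp, where miR-221 and miR-34b remained. Nor was it with only the M-coded spontaneous carcinomas (miR-194, miR-34b and miR-34c remained) or the raised floor (miR-221, miR-34b and miR-34c remained). With normexp background correction, miR-194 lay lower in radiation-induced carcinomas and passed in that direction (log2 -0.47, limma adjusted p = 0.00428). Leaving out single arrays ended the miR-194 call against spontaneous carcinomas for 11 of 23 arrays.

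**Figure D2:**
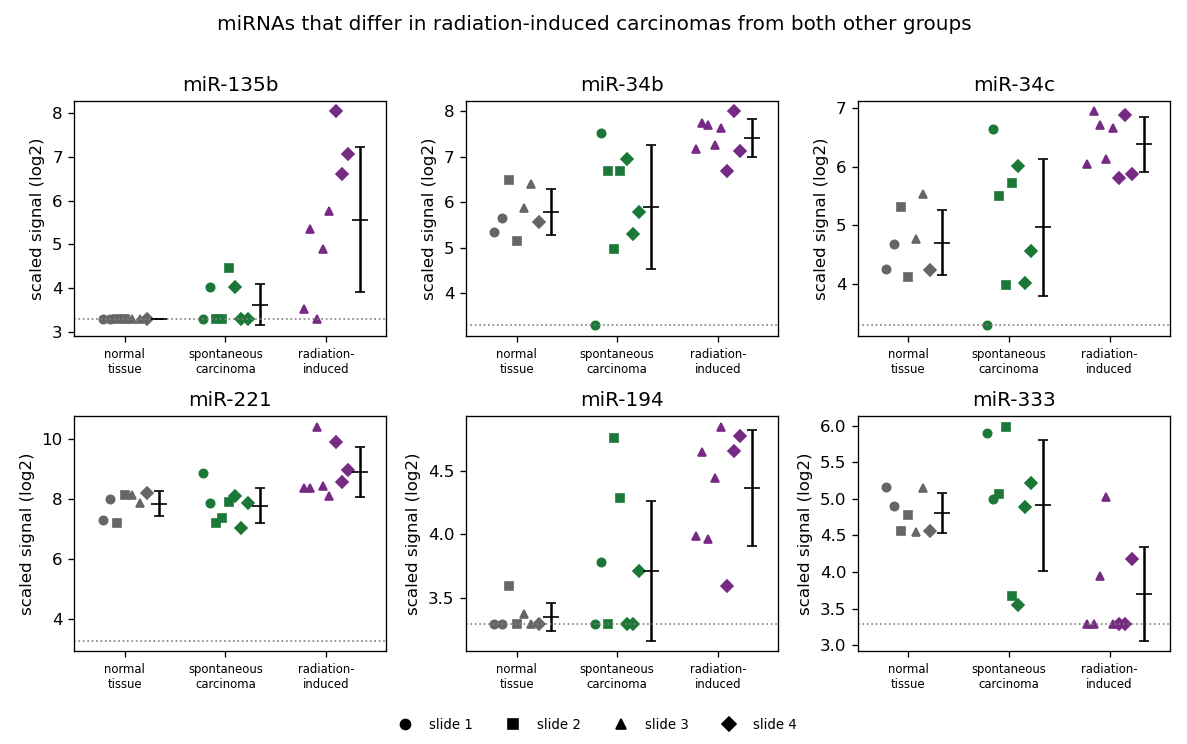
Scaled log2 signal of the 6 radiation-specific miRNAs on each array by group, with the marker shape giving the slide, the bar giving mean ± SD and the dotted line the floor (3.29). miR-135b was at the floor in all 7 normal tissues, and miR-194 lay between 3.29 and 4.85 on all arrays.

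Compared with normal tissue, radiation-induced carcinomas had less of miR-10b, miR-10a-5p, miR-196b and miR-196a, which lie in the Hox gene clusters, by 5.48-fold (log2 -2.46 ± 0.37, SE, n = 8 and 7), 4.73-fold, 4.81-fold and 4.23-fold. The other tested miRNA of these clusters, miR-196c, picked after its values were seen, did not pass (log2 -0.77 ± 0.48, adjusted p = 0.252). The largest fall was in miR-327 (6.08-fold, log2 -2.60 ± 0.68). The muscle miRNAs miR-133b and miR-1 fell 3.69-fold and 2.14-fold and were detected in 2 of 8 and 1 of 8 carcinomas (miR-1 without normal tissue 2 at log2 -0.73, adjusted p = 0.0621), and miR-150, abundant in lymphocytes, 3.02-fold. These were 2 of 4 tested striated muscle members (camera adjusted p = 0.513 with an estimated correlation) and 1 of 7 leukocyte members. The leukocyte median was -0.20 (camera adjusted p = 0.836 with an estimated correlation). miR-135b was at least about 4.84-fold higher, since it was not well above background in any normal tissue, and miR-34c and miR-34b rose 3.20-fold and 3.09-fold. miR-221 rose 2.07-fold (log2 1.05 ± 0.33).

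In all, 33 miRNAs were higher and 17 lower (17 and 12 by at least 1 on the log2 scale, 75 at an unadjusted p under 0.05). The other leading rises were miR-211, miR-598-3p, the hypoxia-induced miR-210 (2.83-fold), miR-674-3p (1.49 ± 0.24), miR-181d, miR-93, miR-181c, miR-19a and miR-425 (1.05 ± 0.23). miR-211 was detected in 4 of 7 normal tissues and miR-598-3p in 5 of 7, near the floor, and miR-196a in 3 of 8 carcinomas. Rises had adjusted p from 0.000145 to 0.0491 in at least 7 of 8 carcinomas, and falls from 4.33e-05 to 0.0405 in at least 7 of 8, except miR-196a in 6 of 8. Of 4 endothelial members, miR-126, miR-126* (log2 -1.37 ± 0.33) and miR-139-5p (-1.27 ± 0.20) fell, as adjusted over the list alone, and miR-139-3p (-0.50 ± 0.68, from -0.91 to -0.24 with single arrays left out) did not pass (camera adjusted p = 0.00803, and adjusted p = 0.513 with an estimated correlation). Of 11 members of the miR-17 to miR-92 cluster and its paralogues, 5 rose, and 10 adjusted over the list alone, led by miR-93 (log2 1.28 ± 0.25), miR-106b, miR-25 and miR-19a (camera adjusted p = 0.00803, and adjusted p = 0.611 with an estimated correlation). In the p53-responsive list 4 of 8 rose, and 6 adjusted over the list alone (camera adjusted p = 0.0203, and adjusted p = 0.513 with an estimated correlation). These were miR-34b, miR-34c, miR-192 and miR-194, and both tested members of the miR-192, miR-194 and miR-215 list rose, also adjusted over the list alone (camera adjusted p = 0.0459, and adjusted p = 0.513 with an estimated correlation). That list holds the miRNA in the study's title, so its count is not taken as independent evidence. With slide as a block the medians of these lists were -1.20 (endothelial), 1.14 (miR-17 to miR-92), 0.94 (p53-responsive) and 1.13 (miR-192), and on slides 3 and 4 they were -1.03 and -1.45, 0.69 and 0.70, 1.03 and 1.097, and 1.04 and 1.097.

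A slide block gave 28 calls (17 higher, 11 lower), 27 of them among the 50. Within slide 3 (5 and 2 arrays) and slide 4 (3 and 1) limma called 0 (28 and 18 at an unadjusted p under 0.05), and all 50 differences, called with these arrays included, had the same direction on both. Leaving out the other group gave 76 calls, and leaving out the 2 carcinomas lacking miR-200 gave 95. The higher and lower calls were 16 and 19 with the percentile over all probes, 16 and 20 with quantile normalization, 14 and 25 with the total gene signal, 4 and 23 unscaled, 3 and 22 in the deposited table and 31 and 9 with normexp.

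Spontaneous carcinomas also had less of these 4 Hox cluster miRNAs than normal tissue: miR-196a fell 7.54-fold (log2 -2.91 ± 0.71, SE, n = 8 and 7), miR-10a-5p 6.12-fold, miR-10b 5.79-fold and miR-196b 4.57-fold. Again miR-196c did not pass (log2 -0.88 ± 0.48, adjusted p = 0.149). The fibroblast miRNAs miR-199a-3p, miR-199a-5p and miR-214 fell 4.03-fold, 3.49-fold and 3.05-fold. The proliferation-linked miR-18a, miR-93, miR-17-5p, miR-20a and miR-19a rose 5.90-fold, 4.19-fold, 3.83-fold, 3.37-fold and 3.33-fold. miR-483 was at least about 13.2-fold higher, as it was not well above background in any normal tissue. It was detected in 6 of 8 carcinomas, so this bound is approximate.

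In all, 52 miRNAs were higher and 29 lower (31 and 21 by at least 1 on the log2 scale, 96 at an unadjusted p under 0.05). The other leading rises were miR-130b (log2 2.50 ± 0.72), miR-207 (detected in 1 of 7 normal tissues), miR-484, miR-210, miR-466b and miR-672 (1.70 ± 0.38), and the other leading falls miR-150 (-2.17 ± 0.53), miR-335 (0.11 with normexp), miR-126, miR-126* and miR-195 (-1.54 ± 0.42). Rises had adjusted p from 2.47e-06 to 0.0159 in at least 7 of 8 carcinomas, except miR-207 in 5 of 8, and falls from 2.47e-06 to 0.037 in at least 7 of 8. miR-192 rose (log2 0.59 ± 0.18, adjusted p = 0.0115, 8 of 8), but lay lower unscaled (-0.67) and in the deposited table (-0.70). Of the miR-17 to miR-92 cluster and its paralogues, 10 of 11 rose, as adjusted over the list alone, miR-106b (log2 1.57 ± 0.23) among them (camera adjusted p = 0.000384, and adjusted p = 0.516 with an estimated correlation). Of 4 endothelial members 3 fell, as adjusted over the list alone, while with normexp miR-126* and miR-139-5p were at 0.28 and 0.42 and the list's median went from -1.55 to 0.35 (camera adjusted p = 0.0166, and adjusted p = 0.513 with an estimated correlation). The fourth, miR-139-3p, was at 0.28 ± 0.68 (from 0.042 to 0.54 with single arrays left out, -0.29 with slide as a block and -1.22 with the brightness covariate) and below 0 with each alternative scaling, signal or table except normexp (-1.07 unscaled). miR-139-5p, not well above background in any spontaneous carcinoma, was at least 1.69-fold lower. In the smooth muscle and fibroblast list 4 of 6 fell, as adjusted over the list alone (camera adjusted p = 0.00803, and adjusted p = 0.513 with an estimated correlation). In the miR-99a, miR-100 and miR-125b list 3 of 4 fell, miR-100 by 2.47-fold, miR-99a by 2.46-fold and miR-125b-5p by 2.14-fold, and miR-99a* (log2 -0.70 ± 0.33, 0.62 with normexp and 0.015 with the raised floor) did not pass except adjusted over the list alone, where 4 fell (camera adjusted p = 0.0166, and adjusted p = 0.513 with an estimated correlation). With slide as a block the medians were 1.57 (miR-17 to miR-92), -1.60 (endothelial), -1.67 (smooth muscle and fibroblast) and -1.34 (miR-99a). On slides 1, 2 and 4, whose arrays are among those the lists were picked on, they were 2.25, 1.82 and 0.64, -2.06, -1.39 and -1.60, -1.35, -1.93 and -2.03, and -1.60, -0.99 and -1.21.

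Slide as a block gave 78 calls, 76 of them among the 81. On slide 2 (3 and 2 arrays) limma called 21 higher and 7 lower, and on slides 1 (2 and 2) and 4 (3 and 1) it called 0 (33 and 18 at an unadjusted p under 0.05), with 81, 79 and 80 of the 81 differences, called with these arrays included, in the same direction. Without the 2 carcinomas lacking miR-200 the count was 102, and with the brightness covariate it was 4. The higher and lower calls were 25 and 57 with the percentile over all probes, 26 and 44 with quantile normalization, 27 and 58 with the total gene signal, 4 and 112 unscaled, 4 and 105 in the deposited table and 123 and 22 with normexp.

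Both kinds of carcinoma differed from normal tissue in the same direction in 33 miRNAs, 22 higher and 11 lower, and none was called in opposite directions. The differences of the 2 comparisons correlated across miRNAs, which are not independent, at r = 0.69 with a covariance of 0.55. Both share the 7 normal tissues. Simulated unchanged groups, with the normal tissues simulated too, gave a mean r of 0.20 (highest 0.44), a covariance of 0.029 and 0 shared calls. Their noise was independent between miRNAs, without slide or brightness differences, so these values do not show what shared technical effects give. Independent lists of these sizes would share 8.62 higher and 2.48 lower. With the normal tissues split so that each comparison had its own, r was 0.70 and 0.54, the covariance 0.57 and 0.47, and the shared calls 11 and 11. The shared higher and lower calls were 5 and 16 with the percentile over all probes, 4 and 15 with quantile normalization, 7 and 19 with the total gene signal, 0 and 23 unscaled, 0 and 21 in the deposited table and 28 and 5 with normexp, so their balance turned with the scaling, signal and background used. The shared count was 21 with slide as a block, 65 without the 2 carcinomas lacking miR-200 and 4 with the brightness covariate.

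**Figure D3:**
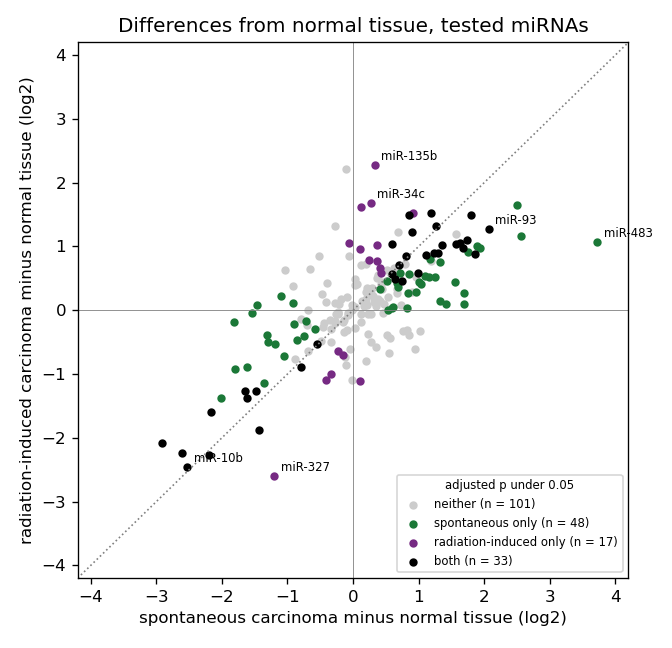
Log2 difference from normal tissue of spontaneous (horizontal) and radiation-induced carcinomas (vertical) for the 199 tested miRNAs, coloured by which comparison passed, with the dotted line marking equal differences. Of them 33 passed in both, 48 in spontaneous and 17 in radiation-induced carcinomas alone, and 101 in neither.

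The other lists passed with neither correlation between radiation-induced and spontaneous carcinomas, and their medians (log2) are given with camera's adjusted p at an estimated correlation. The epithelial miR-200 family was at 0.044 (adjusted p = 0.974, mean -0.033), the epithelial miR-203, miR-205 and miR-375 at 0.54 (0.887), and the miR-183, miR-96 and miR-182 cluster at -0.41 (0.974), and in these 0 of 5, 0 of 3 and 0 of 3 members passed in limma, adjusted over the list alone too. Endothelial miRNAs were at 0.22 (0.887, median -0.058 without the 2 carcinomas lacking miR-200), leukocyte miRNAs at 0.24 (0.876), erythroid miRNAs at -1.01 (0.704) and nervous tissue miRNAs at -0.12 (0.887), with no member passed over all miRNAs tested or adjusted over the list alone. In the smooth muscle and fibroblast list 2 of 6 rose (0.80, 0.513), and in the adipose list 2 of 8 fell (-0.15, 0.781). In the striated muscle list 1 of 4 rose (-0.57, 0.906), or 1 rose and 1 fell adjusted over the list alone. The only tested liver miRNA, miR-122, was not well above background in any radiation-induced carcinoma (log2 -0.60 ± 0.24), and it fell only when adjusted over the list alone (unadjusted p = 0.0176, adjusted p = 0.0791 over all miRNAs). In the miR-15 and miR-16 family 2 of 4 rose (0.71, 0.591), and in let-7 1 of 10 rose (-0.12, 0.974, though camera's direction was up). In the list of miR-21, miR-31, miR-135b, miR-155 and miR-210, often higher in carcinomas, 1 of 5 tested entries rose (0.59, 0.528), where miR-21* was tested and miR-155 was not. The counts of these 5 lists other than striated muscle were the same adjusted over the list alone. The miR-30, miR-26 and miR-181 families were at 0.018 (0.876), 0.090 (0.887) and 0.062 (0.991, mean -0.029), with no member passed. Of 2 tested members of the Dlk1-Dio3 imprinted region 1 fell (-1.06, 0.528), or 2 adjusted over the list alone, and the miR-290 cluster of embryonic stem cells had no tested member. With slide as a block and within slide 4 these medians were -0.17 and -0.11 (miR-200 family), 0.92 and 1.46 (miR-203, miR-205 and miR-375), -0.52 and -0.038 (miR-183 cluster), 0.38 and 0.21 (endothelial), -0.013 and -0.30 (leukocyte), -0.37 and -1.08 (erythroid) and -0.10 and 0.024 (nervous tissue). They were 0.97 and 0.81 (smooth muscle and fibroblast), -0.11 and -0.081 (adipose), -0.37 and -0.61 (striated muscle), 0.63 and 0.38 (miR-15 and miR-16), -0.15 and -0.14 (let-7) and 0.22 and 1.46 (the miR-21 list). The miR-30, miR-26 and miR-181 families were at 0.046 and 0.13, 0.21 and 0.24, and -0.062 and 0.22, the Dlk1-Dio3 region at -0.99 and -0.47, and the miR-192 list at 0.66 and 0.77. With the alternative scalings, signals and background correction, 11 of these 18 medians changed sign in at least 1. Against normal tissue, median and camera differed in sign for the miR-200 family in both kinds of carcinoma (0.35 in radiation-induced and 0.29 in spontaneous, direction down), the miR-29 family in radiation-induced (0.10, down) and the erythroid (0.17, down) and miR-34 lists (0.11, down) in spontaneous carcinomas. Without the 2 carcinomas lacking miR-200 the median of that family was 1.42 in radiation-induced and 1.44 in spontaneous carcinomas, with direction up. In each, limma then called 5 of 5 members higher instead of 0 of 5, but those 2 were left out because these members were at the floor in them, so the calls follow in part from that choice. Camera with an estimated correlation did not pass (adjusted p = 0.539 and 0.559). On slides 1 and 3, which hold those 2 carcinomas, its median was -2.68 in spontaneous and -0.56 in radiation-induced carcinomas, against 1.71 and 0.93 in spontaneous carcinomas on slides 2 and 4 and 1.08 in radiation-induced ones on slide 4. Over all 75 list tests camera called 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 15 with a preset correlation of 0.01.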

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

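The tests of slides, of the carcinomas without the miR-200 family and of miR-194 were chosen after those results were seen, and the slide test was changed from called miRNAs to those with the smallest p because limma called 0 on slides 1 to 3; brightness as a covariate was added after the data were seen but before its own result. Single arrays stood apart from their group in 41 of 222 groups of values. Chance gives about 1 in 20, but not where values pile up at the floor or where miRNAs were named for standing apart. The miR-200 family, named because 2 arrays lacked it, gave 10 of 15, other groups with more than 1 value at the floor 9 of 37, and the remaining groups 22 of 170. Of the 41, 17 lay in radiation-induced carcinoma 3 and 11 in spontaneous carcinoma 1.

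In both carcinomas miR-141, miR-200a, miR-200b, miR-200c and miR-429 were at the floor (log2 3.29), far below the nearest other sample of the group. Spontaneous carcinoma 1 was further apart in miR-18a (10.33), miR-222 (5.56), miR-335 (6.34), miR-484 (7.33), miR-34a (6.59) and the share of signal in the 10 brightest miRNAs (42.4%). Radiation-induced carcinoma 3 was apart in miR-199a-3p (13.51), miR-199a-5p (12.41), miR-214 (12.12), miR-10b (10.02), miR-126* (6.02), miR-351 (4.29), miR-106b (8.90), miR-19a (6.59), miR-20a (8.47), miR-25 (8.48), miR-181d (5.73) and miR-29b (10.73).

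A poor array is argued against for the 2 carcinomas without the miR-200 family, since they detected 167 and 191 miRNAs, within the range of the other arrays of their groups. In each, miR-200c lay at the floor, 6.63 (log2) below the lowest normal tissue. On spontaneous carcinoma 1 the lowest signal well above background was 15.1, above the floor of 9.81, so its gap may be smaller. Both samples were picked for lacking this family, so the gap gives no independent evidence against normal mammary tissue in their place. Radiation-induced carcinoma 3 had a mean correlation of 0.837 with normal tissues and 0.756 with its own group. For spontaneous carcinoma 1 these were 0.648 and 0.639. Normal mammary tissue in their place thus stays undecided. The test took fewer epithelial cells to put all 4 lists of other cell types above the mean of the other carcinomas of the group. A gain of only 1 other cell type would not do so, and failing the test does not argue against fewer epithelial cells. Neither sample showed this, and neither had 1 such list above and another below all other carcinomas of its group. Fewer epithelial cells thus cannot be told apart from other sources. Relative to the other carcinomas of its group, spontaneous carcinoma 1 was at -1.96 in the leukocyte list (below all others), and within their range in the smooth muscle and fibroblast (0.97), endothelial (-0.40) and adipose lists (-0.33), while radiation-induced carcinoma 3 was above all others in the smooth muscle and fibroblast (1.71) and adipose lists (0.38), and within their range in the endothelial (0.75) and leukocyte lists (-0.31). No biological explanation was tested, as the labels give these samples no group of their own.

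Other arrays that stood apart were normal tissue 5 in miR-340-5p (5.44), miR-351 (4.08), miR-450a (5.69) and miR-503 (7.41), normal tissue 3 in miR-194 (3.59) and miR-672 (8.11), normal tissue 2 in miR-1 (6.66) and normal tissue 1 in miR-211 (3.35). Among carcinomas these were radiation-induced carcinoma 4 in miR-1 (3.60) and miR-672 (8.51), radiation-induced carcinoma 1 in miR-133b (3.52), spontaneous carcinoma 7 in miR-29a* (3.58) and radiation-induced carcinoma 2 in its 75th percentile before scaling (2032).

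The calls between radiation-induced and spontaneous carcinomas lie on slides that mostly hold 1 kind of carcinoma, and the spontaneous arrays were dimmer. The 36 miRNAs with the smallest p on slides 1 to 3 had a median difference of 1.21 there and 0.53 on slide 4, in the same direction for 31 of 36. The 1.21 is raised because they were picked on those arrays, so the lower value on slide 4 need not come from slides. Another split of the 6 carcinomas on slide 4 gave 0.70, so the 0.53 does not stand out there either. The test thus cannot tell slide differences apart from the groups. With array brightness as a covariate the median difference of the 36 calls went from 1.19 to 0.80 and its SE from 0.30 to 0.41, ending all calls with 36 of 36 in the same direction, so dim arrays cannot be told apart from the groups either, as brightness went with the group. The origin of the carcinomas, which the design names, stays open as untested.

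The higher miR-194 in radiation-induced carcinomas (log2 0.65 ± 0.22) rests on values near the floor, so a detection limit of dim arrays may account for it. With the floor raised to 4.89 the difference was 0, but no array had miR-194 above 4.85, so this decides nothing. With slide as a block it was 0.78 ± 0.28, its unadjusted p went from 0.00671 to 0.0121 and its adjusted p from 0.0422 to 0.101. The p with the block adjusted among the other miRNAs without it gave 0.0615, and the converse 0.0785, so either its own larger p or the changed adjustment was enough to end the call. Neither explanation can be told apart from a difference between the carcinomas.

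Other groupings of the same arrays rarely gave as many calls. Among 100 splits, 1 gave as many calls as the real one, itself included, for radiation-induced against spontaneous carcinomas (36, highest other 19). The same held for radiation-induced against normal (50, highest other 1) and spontaneous against normal (81, highest other 3). With this fit, a random grouping of the arrays is thus argued against for these counts. The 36 rest on a spread that includes the normal tissues. On the carcinomas alone limma called 0, a count that no split could fall below. The splits ignored slide, so they exclude no slide differences, and a slide block gave 7, 28 and 78 calls. For the 6 radiation-specific miRNAs 2 of 100 splits gave as many, a share under 0.05. The highest other gave 8, more than the real one, so a random grouping is not excluded for them. A slide block left 1 and the compared groups alone 0.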

How the results depend on the processing

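The alternatives named as added below were chosen after the data were seen. No paired analysis was possible because the carcinomas came from different animals and sample numbers pair none of the groups. Scan as a block was not run apart from slide, which it equals. Signal over background limits the dimmest miRNAs and arrays, and the cause of a change was not tested unless stated.

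For radiation-induced against spontaneous carcinomas the 36 calls became 20 with quantile normalization, 99 without scaling, 108 with normexp, 99 in the deposited table, 23 with no filter, 23 for miRNAs detected on all arrays, 61 with array weights, 7 with slide as a block, 0 with only the arrays of the groups compared (58 at an unadjusted p under 0.05 in limma), and 10 with the M-coded spontaneous carcinomas, which leave the 3 on slide 4. Among the added alternatives they became 23 without the carcinomas lacking miR-200 and with slide as a block, 19 with the raised floor and 0 with the brightness covariate (16 unadjusted). Leaving out single arrays gave 20 to 47.

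For radiation-induced carcinomas against normal tissue the 50 calls became 27 unscaled, 25 in the deposited table, 33 for miRNAs detected on all arrays, 117 with array weights, 28 with the slide block and 76 with the compared groups alone. Added alternatives gave 95 without the carcinomas lacking miR-200, 79 with the slide block too and 28 with the raised floor. For spontaneous carcinomas against normal tissue the 81 calls became 145 with normexp and, added, 4 with the brightness covariate. Leaving out the scaling moved the median difference by 0.83, -0.36 and -1.21 (log2) in the 3 comparisons, the deposited table by 0.86, -0.34 and -1.26, and normexp by -0.40 in the first and 0.40 in the last.

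The 6 radiation-specific miRNAs became 3 in the deposited table, 1 for miRNAs detected on all arrays, 24 with array weights, 1 with the slide block and 0 with the compared groups alone. Added alternatives gave 15 without the carcinomas lacking miR-200, 3 with the raised floor and 0 with the brightness covariate, and single arrays left out gave 5 to 11. The 33 miRNAs shared against normal tissue became 21 with the percentile over all probes, 19 with quantile normalization, 21 in the deposited table, 76 with array weights and 21 with the slide block. Added alternatives gave 65 without the carcinomas lacking miR-200, 57 with the slide block too, 21 with the raised floor and 4 with the brightness covariate.

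The miR-194 difference of 0.65 between carcinomas stayed positive without passing with the mean of all probes (0.33), no filter (0.65, more miRNAs tested), the slide block (0.78), the compared groups alone (0.65), without the carcinomas lacking miR-200 and with the slide block (0.78) and the brightness covariate (0.61). It was 0 with the raised floor and reversed with normexp (-0.47), where it passed in the opposite direction (limma adjusted p = 0.00428). Single arrays left out gave 0.58 to 0.80. Over 18 alternatives its adjusted p ran from 0.00168 to 1, and with single arrays left out from 0.0176 to 0.0839. The list tests went from 0 to 15 with the preset correlation, and the array measures past the threshold from 4 to 0 with the M-coded spontaneous carcinomas.

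Of 85 other named miRNA calls, the slide block kept 59 and lost 26, the compared groups alone kept 58, no scaling kept 48 and the brightness covariate kept 27. Between carcinomas, unscaled values reversed miR-107 (0.38) and miR-93 (0.15), the deposited table miR-107 (0.37) and miR-93 (0.13), and normexp miR-145 (-0.10), miR-192 (-0.47), miR-222 (-0.28), miR-29a* (-0.52) and miR-99a* (-0.47). For spontaneous carcinomas against normal tissue, miR-192 reversed unscaled (-0.67) and in the deposited table (-0.70), normexp reversed miR-126* (0.28), miR-139-5p (0.42), miR-335 (0.11) and miR-99a* (0.62), and the brightness covariate reversed miR-466b (-0.033).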

Other observations

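The miRNAs described here were chosen after their values were seen. Spontaneous carcinoma 1 had several miRNAs at levels above those of all other arrays. Brain-enriched miR-124 was at log2 8.21 and at the floor (3.29) on all other arrays, and miR-9 and miR-9* were at 7.18 and 7.52, with highest other levels of 5.69 and 5.70. miR-188 was at 10.30 (highest other 6.58), miR-130b at 10.05 (7.41) and miR-301b at 7.83 (3.72). The epithelial miR-205 and miR-375 were at the floor in it, and miR-204 too, against means of 9.20, 8.19 and 9.56 in the other spontaneous carcinomas. Its best correlation with any array was 0.701.

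Radiation-induced carcinoma 3 had the fibroblast-linked miR-199a-5p at 12.41 and miR-214 at 12.12, above all other arrays, normal tissues included (highest 10.84 and 10.35). miR-183, miR-96, miR-203 and miR-31 were at the floor, against means of 8.48, 9.64, 8.15 and 9.11 in the other radiation-induced carcinomas. It correlated best with a normal tissue (0.862).

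Among the spontaneous carcinomas, limma called 0 miRNAs between the 5 with K codes and the 3 with M codes (8 at an unadjusted p under 0.05). The 5 with K codes lie on slides 1 and 2 and the 3 with M codes on slide 4, so code letter and slide cannot be separated. What the letters stand for is not given in the sources used here.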
